A study of Mus musculus with 23 samples.

How the data were processed

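RNA of bone marrow-derived macrophages from wild-type C57BL/6 mice was measured on 23 arrays in 6 groups. Per the labels, cells were grown from marrow with M-CSF at 10 ng/mL for 6 days and treated 1 to 3 days after its removal, and about 10 ng of RNA per sample was amplified and labelled with biotin. The fatty acids were bound to fatty acid-free BSA, which alone served as vehicle.

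The deposited values are log2 expression per probe set, with 1 column per array, made by RMA per the submitters' processing notes. RMA corrects background, brings arrays to a common distribution and summarises probes. The notes also name limma, and give neither versions nor the role of limma, so both remain unknown here. The values ran from 0.380 to 12.9, no value was negative or missing, no pair of arrays was identical, and array medians lay between 3.98 and 4.12, which fits the log2 scale. Arrays give intensities, so the number of arrays per group, 3 or 4, limits the precision.

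Of 35556 probe sets, 21789 carried 1 gene symbol in the probe table, 1621 carried several and 12146 were not in the table. The probe sets with 1 symbol were used, with the probe set of highest mean taken for each of the 999 genes that had more than 1, which left 19938 genes. Symbols were checked against the reference through the Entrez identifier for 21698 probe sets, and none had to be updated. The other probe sets entered only the alternative that tested every probe set and a count of changed probe sets.

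A linear model with a mean for each of the 6 groups was fitted to every gene with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variance. P-values were two-sided and adjusted over the genes of each comparison by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. The 11 comparisons were SA against OA at each time, the change of that difference between the times (interaction), and SA, OA and LPS against vehicle at 5 h. They also included SA and OA at 20 h against vehicle at 5 h, each acid at 20 h against 5 h, and SA against LPS at 5 h. No vehicle of 20 h is among the groups, so comparisons of 20 h with vehicle combine treatment and time.

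For gene groups, 31 lists with 635 genes, of which 583 were measured, were fixed before the data were examined. So were the comparisons, the gene and list tests, the rule for naming genes and all alternatives but 1. Several tests of explanations were chosen after the results were seen and are marked as such below. The lists cover the branches of the unfolded protein response, lipid and sterol metabolism, inflammation, stress responses, cell growth and death, organelles, macrophage states, housekeeping genes and markers of other cell types. The 30 lists with at least 3 measured members were tested with camera, a competitive test that compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. The same test was run with a correlation estimated for each list. List p-values were adjusted over the lists of a comparison, and members were also adjusted over the list alone. No list past the test had a median, a mean and a test of different sign. The LPS-responsive genes, 100 risen and 100 fallen, were chosen on the LPS and vehicle arrays and tested on the fatty acid arrays.

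The genes named were, per comparison, the 6 largest rises and 6 largest falls past the threshold whose groups did not overlap, with overlap not considered for the interaction. Added to these were up to 4 changed members with the largest change in each list past camera or with at least 3 changed members, and 16 anchor genes (Ddit3, Hspa5, Dnajb9, Xbp1, Trib3, Scd1, Plin2, Pdk4, Abca1, Hmgcs1, Il1b, Tnf, Il6, Nlrp3, Ifit1, Hmox1). Groups fail to overlap by chance in 2.86% of comparisons of 4 with 4 arrays and in 5.71% of 4 with 3.

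The alternatives were a variance trend with robust moderation, centring each array on its median, quantile normalisation of the tested genes, array quality weights, leaving out the dimmest 25% of genes, other choices of probe set, all probe sets, a fit of the compared groups alone, a replicate block, and leaving out each array in turn. Member counts without replicate 2 of 20 h SA were added after seeing the data. The fit was also tested on simulated data, drawn from a normal distribution with the mean and spread of each gene, to which known changes were added. For 4 against 4 arrays, 64.2% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and all changes of 2 were recovered, and 4.74% of calls fell on unchanged genes. For LPS against vehicle the shares were 56.7%, 92.5% and 98.5%, with 3.51% of calls on unchanged genes. Genes were drawn independently of each other, and 67, 67 and 66 of 19938 genes were changed by 0.5, 1 and 2. In the data, 3324 genes were called for SA against OA at 20 h and 4464 for LPS against vehicle. The shares may therefore not hold for the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.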

Results

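Gene expression was measured on 23 single-channel arrays in bone marrow-derived macrophages of wild-type C57BL/6 mice. The arrays fell into 6 groups. Vehicle, bovine serum albumin (BSA) at 125 µM, was given for 5 h (n = 3), and lipopolysaccharide (LPS), the bacterial ligand of the receptor TLR4, was given at 1 ng/mL for 5 h (n = 4). Stearic acid (SA), a long-chain saturated fatty acid, and oleic acid (OA), which has the same chain length and a double bond, were given on BSA at 250 µM. Each acid was given for 5 h or 20 h (n = 4 for each acid and time). The sample labels give 5 h for vehicle and LPS, whereas the series text gives 4 h. The arrays held 35556 probe sets each, with array medians between 3.98 and 4.12 on the log2 scale, and 19938 genes were tested. Replicate 2 of 20 h SA stood apart from its group, with a spread of gene deviations of 0.215 (SD) against 0.153 to 0.161 on the other arrays of that group. The labels call the samples replicate wells and the series design calls them biological replicates, so the p-values measure the spread between these samples, which can be technical. The number of arrays limits the precision. Signal over background was not assessed. Genes with a group mean near or below the array medians in a comparison given here included Bub1, Il6, Il1a, Il1b, Nqo1, Acss2, Scd1, Pdk4, Ccr2, Ccl7, Cxcl3, Ccl17, Ptgs2, Mx1, Cd79b, Derl3, Olr1 and H2ac4, and the size of their log2 changes is uncertain for that reason.

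Whether a saturated and a monounsaturated fatty acid act differently on macrophages after prolonged exposure was addressed by setting SA against OA at 20 h. Clec4e, a C-type lectin receptor of macrophages, was 13.3-fold higher with SA, at a log2 expression of 8.29 ± 0.22 (SD, n = 4) against 4.56 ± 0.22 (SD, n = 4) with OA. Slc7a11, the cystine transporter, was 11.6-fold higher, at 8.95 ± 0.10 (SD, n = 4) against 5.42 ± 0.29 (SD, n = 4), and Acod1, the enzyme that makes itaconate, was 10.2-fold higher. These differences include low levels with OA. Set against the 5 h vehicle, which combines treatment and time, 20 h OA gave -3.29 for Clec4e, -2.07 for Slc7a11 and -3.32 for Acod1. The vehicle levels were 7.84, 7.49 and 8.04. Large falls were measured in the endocytic adaptor Dab2, 8.86-fold lower at 7.02 ± 0.30 (SD, n = 4) against 10.16 ± 0.07 (SD, n = 4) and in the chemokine Ccl2, 7.29-fold lower. The mitotic checkpoint kinase Bub1 also fell, to 2.93 ± 0.43 (SD, n = 4) against 5.95 ± 0.12 (SD, n = 4), with the SA level below the array medians and so not shown to lie above background. The adjusted p was 2.34e-17 for Clec4e, 9.29e-17 for Slc7a11, 8.53e-14 for Dab2 and 1.12e-12 for Bub1. For each of these genes every SA array lay on the same side of every OA array. The rule for naming the largest changes required this, so it is no further support. In all, 1539 genes rose and 1785 fell at 20 h, 454 of them at least 2-fold, with a median SE of 0.12 on the log2 scale. The probe sets behind Clec4e, Slc7a11, Dab2, Bub1, Hspa5 and Ddit3 were 10547664, 10498024, 10422728, 10487480, 10471586 and 10366881.

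Genes of the unfolded protein response were higher with SA than with OA at 20 h. Of 20 chaperones and folding enzymes of the endoplasmic reticulum (ER), 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 0.58 and an adjusted p of 8.91e-16. Hspa5, the main ER chaperone, stood at 10.53 ± 0.10 (SD, n = 4) with SA and 9.24 ± 0.01 (SD, n = 4) with OA, a log2 change of 1.29 ± 0.07 (SE). Of 21 targets of XBP1 and of ER-associated degradation, 18 rose and none fell (18 adjusted over the list alone, median 0.66, adjusted p = 2.79e-21). The ER co-chaperone Dnajb9 rose by 1.71 ± 0.10 (SE) and Derl3 by 1.97 ± 0.17 (SE). Of 36 targets of the PERK, ATF4 and CHOP branch, 24 rose and 1 fell (28 and 1 adjusted over the list alone, median 0.74, adjusted p = 3.50e-22). Ddit3, which encodes the stress transcription factor CHOP, stood at 8.91 ± 0.09 (SD, n = 4) against 6.99 ± 0.07 (SD, n = 4), and Ppp1r15a, which restores translation under stress, rose by 2.05 ± 0.13 (SE). NRF2 targets rose as well, 13 of 19 with none fallen (13 adjusted over the list alone, median 0.73, adjusted p = 1.63e-14). Nqo1, a quinone reductase, rose by 2.24 ± 0.22 (SE) and Gclm, a subunit of the enzyme that limits glutathione synthesis, by 1.83 ± 0.08 (SE). Part of the NRF2 difference lay with OA. Set against the 5 h vehicle, which combines treatment and time, Gclm changed by -1.15 with 20 h OA. Of the 19 NRF2 targets, 7 fell and none rose with 20 h OA (median -0.05), and 11 rose and none fell with 20 h SA (median 0.45). The tests of these 4 lists also passed with an estimated correlation, at adjusted p values of 0.00051, 0.000223, 0.000223 and 0.000223. Without replicate 2 of 20 h SA, an alternative added after seeing the data, 15, 19, 24 and 13 members of the 4 lists rose, with medians of 0.61, 0.70, 0.78 and 0.74. Of 10 transcripts that IRE1 is known to degrade, 4 fell and none rose (4 adjusted over the list alone, median -0.14, adjusted p = 0.0137, adjusted p = 0.169 with an estimated correlation). Against the 5 h vehicle, which combines treatment and time, 2 rose and 3 fell with 20 h SA (median 0.06, adjusted p = 0.804). With 20 h OA 2 rose and none fell (median 0.13, adjusted p = 0.0264, adjusted p = 0.224 with an estimated correlation).

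**Figure D1:**
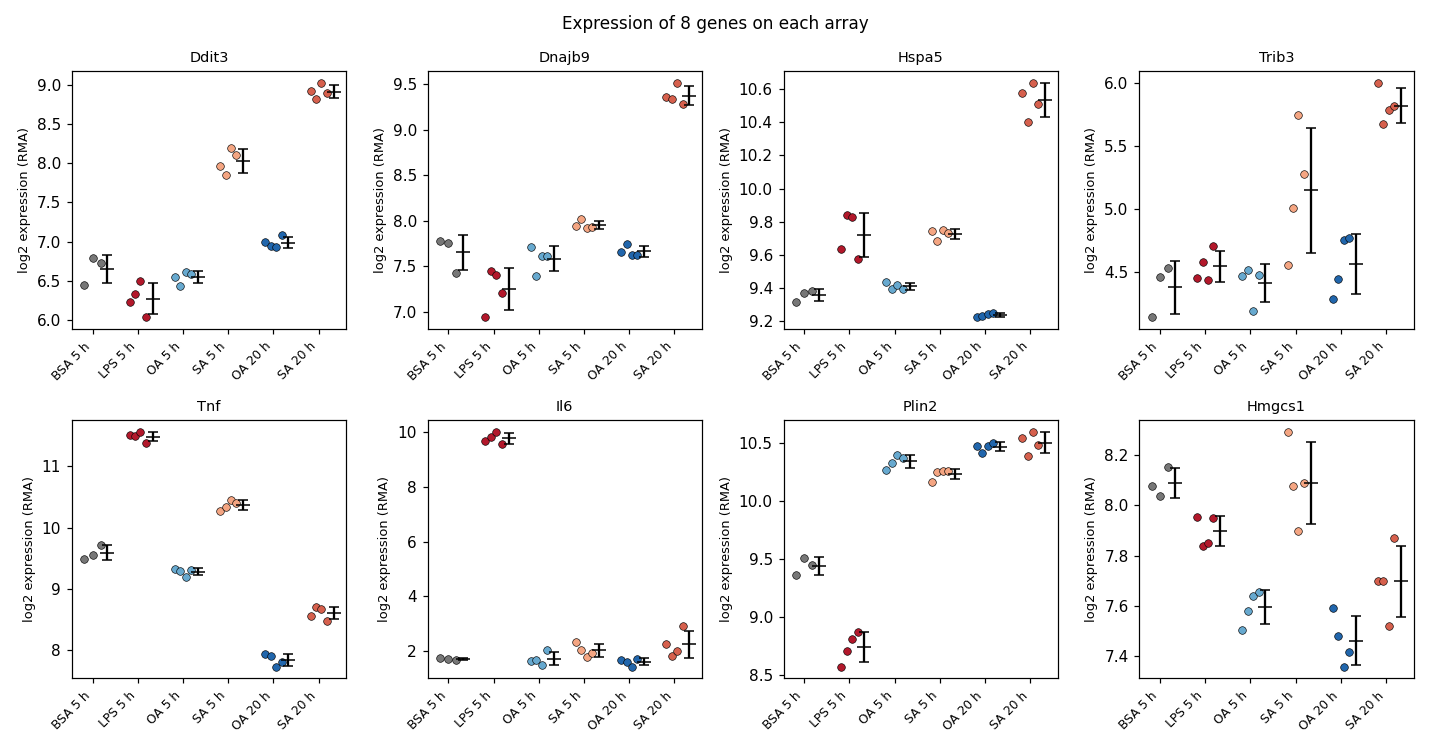
Log2 expression of 8 genes on each array (points) with the group mean and SD (bars), by treatment and time. Hspa5 and Dnajb9 were highest after 20 h of SA, Ddit3 was higher with SA than with OA at both times, and Il6 was highest with LPS.

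Cell cycle genes and genes of macrophage identity were lower with SA than with OA at 20 h. All 29 measured cell cycle genes fell (29 adjusted over the list alone), with a median log2 change of -1.37 and an adjusted p of 6.46e-49. The DNA topoisomerase Top2a changed by -2.50 ± 0.11 (SE), cyclin A2 (Ccna2) by -2.39 ± 0.09 (SE) and cyclin D1 (Ccnd1) by -2.60 ± 0.13 (SE). Of 20 macrophage identity genes, 12 fell and none rose (15 adjusted over the list alone, median -0.44, adjusted p = 1.63e-14). The fractalkine receptor Cx3cr1 and the Fc receptor Fcgr1 each changed by -2.13 ± 0.12 (SE) and the transcription factor Maf by -1.22. Of 17 genes of alternative activation, 4 fell and none rose (5 adjusted over the list alone, median -0.07, adjusted p = 0.0137), including the mannose receptor Mrc1 at -2.13 ± 0.12 (SE) and fibronectin (Fn1) at -1.37. The median of this list was -0.04 without replicate 1 of 20 h SA or replicate 4 of 20 h OA. These 3 lists also passed with an estimated correlation, at adjusted p values of 8.86e-06, 8.39e-05 and 0.0388. Markers of other cell types were measured beside them: of 72 markers of dendritic cells, neutrophils, lymphocytes, erythroid cells, mast cells and stromal cells, 1 rose and 4 fell. The lists of 5 of these 6 cell types had a mean below the median of the tested genes with OA, from 2.98 to 4.09 against 4.27, and the neutrophil list stood above it. Without replicate 2 of 20 h SA, 29 cell cycle genes and 12 macrophage identity genes fell, with medians of -1.40 and -0.46.

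Some of the inflammatory and lipid lists had members that moved both ways at 20 h. Of 40 cytokines and feedback genes driven by NF-kB, 13 rose and 7 fell (14 and 7 adjusted over the list alone, median 0.16, adjusted p = 0.00198). With an estimated correlation the adjusted p was 0.0897, and 0.0444 without replicate 2 of 20 h SA. The neutrophil chemokine Cxcl2 was higher with SA than with OA by 2.77 ± 0.10 (SE) and Tnf by 0.76 ± 0.08 (SE), while Ccl7 changed by -2.62 ± 0.20 (SE). With 20 h OA set against the 5 h vehicle, which combines treatment and time, Cxcl2 changed by -1.92 and Tnf by -1.75. Tnf stood at 8.48 to 8.69 on the 20 h SA arrays, below the 9.49 to 9.72 of the vehicle arrays. Of 19 inflammasome and pyroptosis genes, 4 rose and 10 fell (5 and 13 adjusted over the list alone, median -0.25, adjusted p = 0.0137, adjusted p = 0.272 with an estimated correlation). Il1a rose by 1.60, and Il1b changed by -1.33 ± 0.15 (SE). Of 28 interferon-stimulated genes, 9 rose and none fell (9 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.0137, adjusted p = 0.371 with an estimated correlation). Its adjusted p was 0.0519 without replicate 3 of 20 h OA, and its median was 0.18 without replicate 2 of 20 h SA (adjusted p = 0.00725) and 0.05 without replicate 4. Of 13 LXR targets, 5 fell and 1 rose (7 and 3 adjusted over the list alone, median -0.27, adjusted p = 0.00476, adjusted p = 0.0897 with an estimated correlation). The cholesterol exporter Abca1 changed by -0.72 ± 0.08 (SE) and the phospholipid transfer protein Pltp by -1.58 ± 0.09 (SE). Of 18 genes of fatty acid synthesis and desaturation, 6 rose and none fell (6 adjusted over the list alone, median 0.15, adjusted p = 0.00104, adjusted p = 0.0897 with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, rose by 1.86 ± 0.12 (SE) and the desaturase Scd1 by 1.22 ± 0.19 (SE). Of 19 cholesterol synthesis genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0318, adjusted p = 0.453 with an estimated correlation). Its adjusted p was 0.0636 without replicate 2 of 20 h OA and 0.0939 without replicate 1 or replicate 4 of 20 h SA. Its median was 0.17 without replicate 2 of 20 h SA, where the adjusted p was 0.00519, and 0.07 without replicate 1 of 20 h OA. Of 25 genes of the mitochondrial respiratory chain, 6 fell and none rose (11 adjusted over the list alone, median -0.21, adjusted p = 7.50e-05, adjusted p = 0.279 with an estimated correlation). Without replicate 2 of 20 h SA 5 fell, with a median of -0.11.

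SA and OA were not separated by the test at 20 h for the lipid droplet coat gene Plin2, whose log2 difference was 0.03 (95% interval -0.12 to 0.19, adjusted p = 0.854). The kinase Pdk4 did not pass either, at 0.28 (95% interval -0.03 to 0.59, adjusted p = 0.256). The lipid droplet list, with 2 of 20 members risen, had a median of 0.08 and an adjusted p of 0.113. The PPAR list, with 2 of 29 risen and 9 fallen, had a median of -0.06 and an adjusted p of 0.0577. Medians were 0.00 for phospholipid and sphingolipid synthesis (adjusted p = 0.974), 0.00 for hypoxia and glycolysis (adjusted p = 0.461), 0.10 for p53 targets (adjusted p = 0.704) and 0.07 for lysosomal genes (adjusted p = 0.113, and 0.0465 without replicate 2 of 20 h SA). They were 0.07 for the heat shock list (adjusted p = 0.421), -0.13 for immediate early genes (adjusted p = 0.113) and -0.02 for housekeeping genes (adjusted p = 0.267). Markers of dendritic cells had a median of 0.09 (adjusted p = 0.966), neutrophils -0.02 (adjusted p = 0.421), and lymphocytes 0.09 (adjusted p = 0.937). Those of erythroid cells had a median of 0.03 (adjusted p = 0.567), mast cells 0.04 (adjusted p = 0.974) and stromal cells 0.05 (adjusted p = 0.937). These 6 medians were 0.03, 0.05, 0.02, -0.06, 0.03 and -0.01 without replicate 2 of 20 h SA, and those of the lipid droplet and hypoxia lists were 0.05 and -0.02. The 2 metallothioneins measured, too few for the list test, had a median of -0.07 and neither passed.

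**Figure D2:**
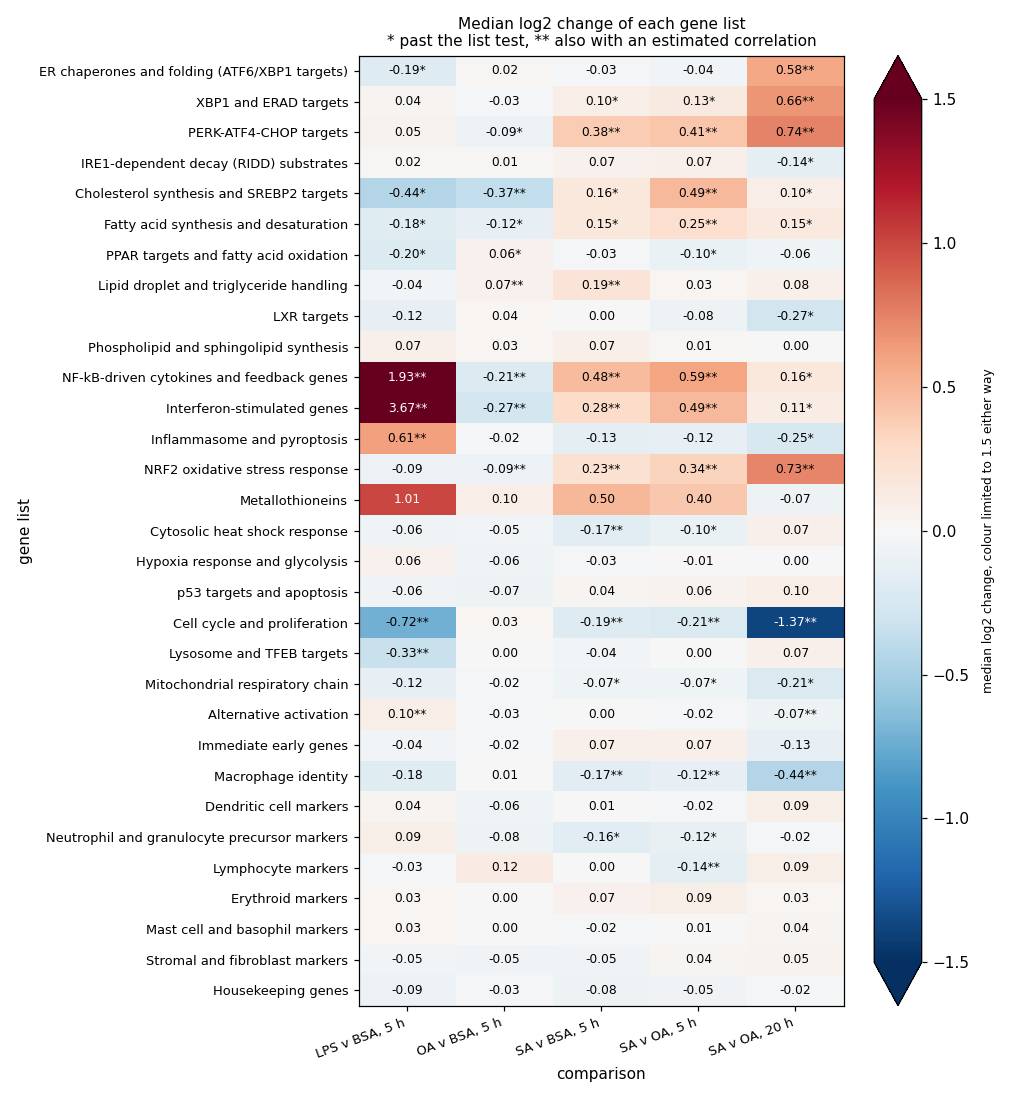
Median log2 change of each of 31 gene lists in 5 comparisons, with asterisks for lists past the list test and colours limited to 1.5 either way. The interferon-stimulated genes had the largest median with LPS, at 3.67, and the cell cycle list the lowest with SA against OA at 20 h, at -1.37.

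The early response to the same acids was compared at 5 h. The chemokines Cxcl2 and Cxcl3 and the prostaglandin synthase Ptgs2 were among the genes that rose most with SA against OA. Cxcl2 stood at 10.72 ± 0.10 (SD, n = 4) with SA and 8.57 ± 0.08 (SD, n = 4) with OA, 4.42-fold higher. Acod1 stood at 9.65 ± 0.21 (SD, n = 4) against 7.45 ± 0.14 (SD, n = 4), 4.60-fold higher. The chemokine receptor Ccr2 changed by -1.19 ± 0.11 (SE) and the proton-sensing receptor Gpr65 by -1.30 ± 0.11 (SE). The adjusted p was 4.96e-13 for Cxcl2, 6.26e-12 for Acod1, 3.53e-08 for Ccr2 and 1.26e-08 for Gpr65. In all, 658 genes rose and 473 fell, 92 of them at least 2-fold, with a median SE of 0.12, and 660 passed in a fit of the SA and OA arrays alone.

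At 5 h, 26 of 40 NF-kB-driven genes rose with SA against OA and none fell (30 adjusted over the list alone, median 0.59, adjusted p = 4.89e-42), including Tnf at 1.08 ± 0.08 (SE). Of the interferon-stimulated genes, 17 rose and none fell (19 adjusted over the list alone, median 0.49, adjusted p = 1.94e-24), and the transcription factor Irf1 rose by 1.72 ± 0.11 (SE). Of 36 targets of PERK, ATF4 and CHOP, 22 rose (25 rose and 1 fell adjusted over the list alone, median 0.41, adjusted p = 1.03e-29). Ddit3 stood at 8.03 ± 0.15 (SD, n = 4) against 6.55 ± 0.07 (SD, n = 4) and the asparagine synthetase Asns rose by 1.26 ± 0.10 (SE). Of 19 cholesterol synthesis genes, 14 rose and none fell (15 adjusted over the list alone, median 0.49, adjusted p = 6.07e-20). Insig1, a regulator of sterol sensing, rose by 1.54 ± 0.09 (SE). Fatty acid synthesis genes rose in 6 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.25, adjusted p = 1.94e-06), and the desaturase Scd2 rose by 1.44 ± 0.10 (SE). NRF2 targets rose in 9 of 19 cases (10 adjusted over the list alone, median 0.34, adjusted p = 4.52e-13). Cell cycle genes fell in 9 of 29 cases (13 adjusted over the list alone, median -0.21, adjusted p = 5.68e-10) and macrophage identity genes in 5 of 20 (6 adjusted over the list alone, median -0.12, adjusted p = 8.26e-07). For the neutrophil markers, none of 16 passed the gene test in limma, over all genes or over the list alone, and the list median was -0.12 (adjusted p = 0.0422, adjusted p = 0.282 with an estimated correlation). The adjusted p of that list was 0.0644, 0.114, 0.0834 and 0.258 without replicate 1 or 2 of OA and replicate 1 or 2 of SA, and its median was -0.19 without replicate 4 of SA. With an estimated correlation the other 8 lists had adjusted p values of 4.93e-07, 0.00134, 9.63e-05, 0.00258, 0.0147, 0.000576, 0.0117 and 0.00258. The difference in cholesterol synthesis genes included a fall with OA. Against vehicle at 5 h, the median of that list was -0.37 with OA and 0.16 with SA. For fatty acid synthesis the medians against vehicle were -0.12 with OA and 0.15 with SA.

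Few genes of the ER chaperone and XBP1 lists passed the test between the acids at 5 h. Of 20 ER chaperones, 1 rose and 1 fell (median -0.04, adjusted p = 0.321). Of the XBP1 and degradation targets 2 of 21 rose (2 adjusted over the list alone, median 0.13, adjusted p = 0.00212, adjusted p = 0.186 with an estimated correlation). The log2 difference of SA from OA was 0.04 for Xbp1 itself (95% interval -0.11 to 0.20), -0.11 for Plin2 (95% interval -0.27 to 0.05) and 0.30 for Il6 (95% interval -0.05 to 0.65). Among PPAR targets 1 rose and 3 fell (median -0.10, adjusted p = 0.0151, adjusted p = 0.278 with an estimated correlation). Angptl4, a lipoprotein lipase inhibitor, changed by -0.93 ± 0.12 (SE). The adjusted p of the list was 0.0600 without replicate 1 of 5 h OA and 0.0547 without replicate 2 of 5 h SA. Of 15 lymphocyte markers, 2 fell (3 adjusted over the list alone, median -0.14, adjusted p = 0.0134, adjusted p = 0.0457 with an estimated correlation). The B cell receptor subunit Cd79b changed by -0.76. The adjusted p of this list was 0.0812 when the dimmest 25% of genes were left out, and its median was -0.20 without replicate 4 of 5 h OA.

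Whether the difference between SA and OA changed with time was tested as an interaction across the 16 fatty acid arrays. ER chaperones gained most among the lists, with a more positive SA effect at 20 h than at 5 h for 14 of 20 and a less positive effect for none (15 adjusted over the list alone, median 0.70, adjusted p = 3.22e-27). Of the XBP1 and degradation targets, 13 of 21 had a more positive effect at 20 h (15 adjusted over the list alone, median 0.52, adjusted p = 2.95e-20). The difference grew by 1.34 ± 0.15 (SE) for Dnajb9 and by 0.98 ± 0.10 (SE) for Hspa5. The NRF2 list gained too, with 6 members up and 1 down (7 and 2 adjusted over the list alone, median 0.28, adjusted p = 3.23e-06). The SA effect on Ccl2 changed by -3.34 ± 0.22 (SE) and that on Bub1 by -2.92 ± 0.24 (SE). Cell cycle genes moved down in 22 of 29 cases (26 adjusted over the list alone, median -1.22, adjusted p = 3.85e-51), and macrophage identity genes in 9 of 20 (10 down and 1 up adjusted over the list alone, median -0.31, adjusted p = 4.02e-10). NF-kB-driven genes moved down in 17 of 40 cases with 2 up (24 and 2 adjusted over the list alone, median -0.43, adjusted p = 6.30e-15). Under an estimated correlation these 6 lists had adjusted p values of 5.38e-05, 0.000315, 0.0139, 6.50e-06, 0.000315 and 0.00022. For the PERK, ATF4 and CHOP list, 6 members moved up and 1 down (9 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.000521, adjusted p = 0.113 with an estimated correlation). For Ddit3 the change was 0.44 with an adjusted p of 0.0796, which was 0.0498 without replicate 3 of 5 h SA, 0.031 with trend and robust moderation and 0.00621 after quantile normalisation. The cholesterol list had 4 members down (7 adjusted over the list alone, median -0.32, adjusted p = 1.02e-06, adjusted p = 0.0709 with an estimated correlation). The interferon list had 7 members down (12 adjusted over the list alone, median -0.30, adjusted p = 6.42e-08, adjusted p = 0.0625 with an estimated correlation). In total 315 genes had a more positive and 677 a more negative SA effect at 20 h, with a median SE of 0.17.

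**Figure D3:**
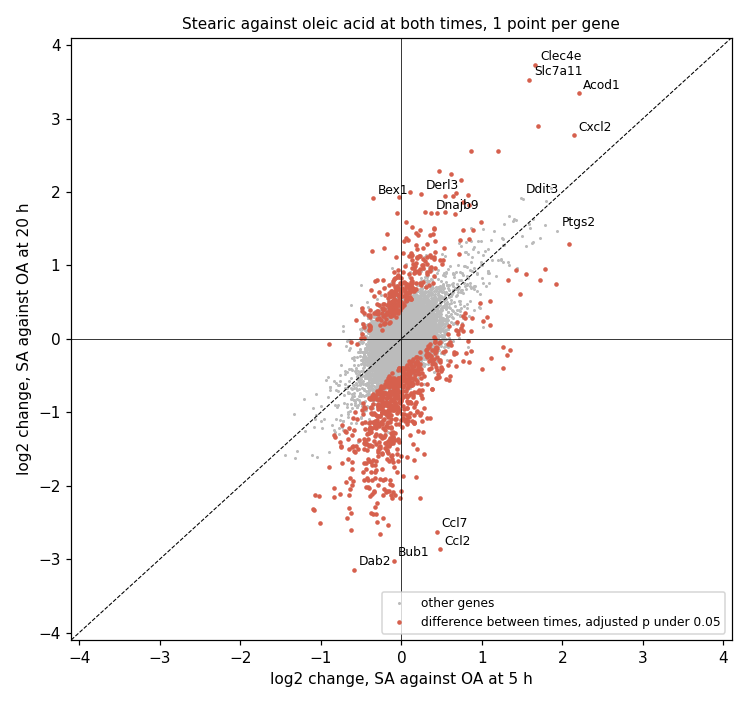
Log2 change of each gene with SA against OA at 5 h (horizontal) and at 20 h (vertical), with genes whose difference between the times passed the test in colour and the line of equal change dashed. Ccl2 and Bub1 lie far below the line, and Clec4e, Slc7a11 and Derl3 lie above it.

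Of the 658 genes that rose with SA against OA at 5 h, 405 also rose at 20 h, where 50.8 would be shared if the calls were independent. Of the 473 that fell at 5 h, 371 also fell at 20 h, against 42.3. Ddit3, Slc7a11, Acod1 and Cxcl2 were higher with SA than with OA at both times. Genes that changed in opposite directions numbered 20 risen then fallen and 6 fallen then risen, against 58.9 and 36.5.

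**Figure D4:**
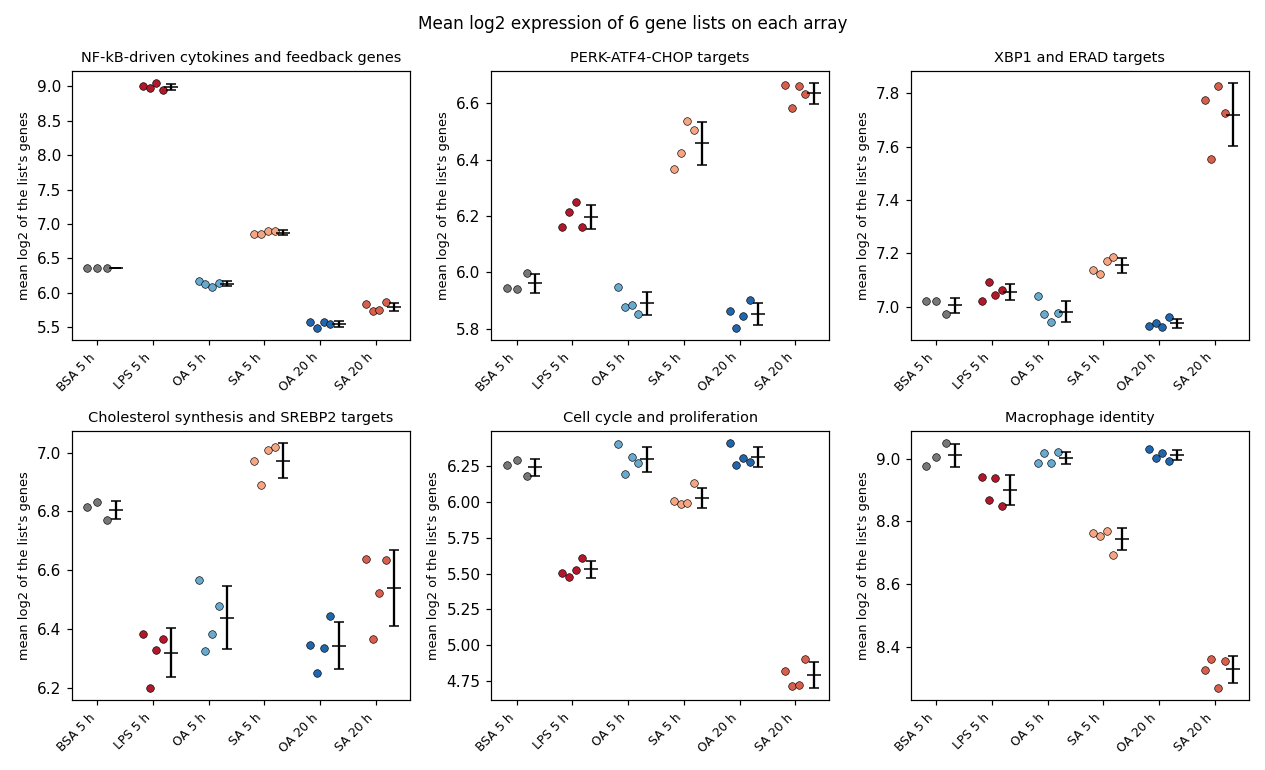
Mean log2 expression of the genes of 6 lists on each array (points) with the group mean and SD (bars), by treatment and time. The cell cycle list stood at 4.79 ± 0.09 (SD, n = 4) after 20 h of SA and at 6.31 ± 0.07 (SD, n = 4) after 20 h of OA.

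Each fatty acid was also set against vehicle at 5 h. Plin2, a marker of lipid loading, rose with both acids, from 9.44 ± 0.07 (SD, n = 3) with vehicle to 10.23 ± 0.05 (SD, n = 4) with SA and 10.34 ± 0.06 (SD, n = 4) with OA. The adjusted p was 8.95e-07 for SA and 2.08e-06 for OA. With SA, the chemokines Cxcl3, Cxcl2 and Cxcl1 rose by 2.18 ± 0.11 (SE), 1.93 ± 0.10 (SE) and 1.92 ± 0.12 (SE), and Ddit3 by 1.37 ± 0.11 (SE). Herpud1 rose by 1.39 ± 0.12 (SE) and Hspa5 by 0.37 ± 0.08 (SE, adjusted p = 0.00716). Of the NF-kB-driven genes 21 of 40 rose and 1 fell (27 and 3 adjusted over the list alone, median 0.48, adjusted p = 1.14e-27). Of the PERK, ATF4 and CHOP targets 19 of 36 rose (23 adjusted over the list alone, median 0.38, adjusted p = 1.35e-26), and of the interferon-stimulated genes 9 of 28 rose (14 adjusted over the list alone, median 0.28, adjusted p = 1.04e-09). The NRF2 list had 8 of 19 risen (8 risen and 1 fallen adjusted over the list alone, median 0.23, adjusted p = 5.28e-08). The lipid droplet list had 3 of 20 risen and 1 fallen (4 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.00312), and the monoglyceride lipase Mgll rose by 1.21 ± 0.12 (SE). Macrophage identity genes fell in 5 of 20 cases (8 adjusted over the list alone, median -0.17, adjusted p = 1.25e-08). Beside them, 1 of 16 neutrophil markers fell (2 adjusted over the list alone, median -0.16, adjusted p = 0.000457, adjusted p = 0.0536 with an estimated correlation). Cell cycle genes fell in 3 of 29 cases (7 adjusted over the list alone, median -0.19, adjusted p = 1.14e-07) and heat shock genes in 2 of 14 (3 adjusted over the list alone, median -0.17, adjusted p = 0.000474). The test with an estimated correlation gave the other 8 lists adjusted p values of 9.87e-06, 0.000191, 0.0334, 0.00581, 0.0148, 0.00123, 0.0321 and 0.0308. The median of the NRF2 list was 0.15 without replicate 3 of vehicle and 0.10 without replicate 4 of SA, and that of the heat shock list -0.11 without replicate 3 of SA. Dnaja1, among the 2 heat shock genes that fell, stood at 0.02 (adjusted p = 0.979) with its probe set of largest variance. Of 19 cholesterol synthesis genes 3 rose and none fell (3 adjusted over the list alone, median 0.16, adjusted p = 0.00239, adjusted p = 0.310 with an estimated correlation). Of 18 fatty acid synthesis genes 3 rose and none fell (7 adjusted over the list alone, median 0.15, adjusted p = 0.00177, adjusted p = 0.103 with an estimated correlation). In total 386 genes rose and 278 fell with SA against vehicle, with a median SE of 0.13. The number that passed was 389 without replicate 2 of vehicle and 373 in a fit of the compared arrays alone.

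With OA against vehicle, 4 genes rose and 10 fell. At an unadjusted p under 0.05, 1128 of the 19938 tested genes passed, where a share of 0.05 would pass by chance. Angptl4 rose by 1.11 ± 0.13 (SE, adjusted p = 8.14e-05) and Cpt1a, which brings fatty acids into mitochondria, by 0.99 ± 0.10 (SE, adjusted p = 4.59e-06). The desaturase Scd2 changed by -0.96 ± 0.11 (SE, adjusted p = 8.14e-05), the acute-phase gene Saa3 by -0.98 ± 0.14 (SE, adjusted p = 0.00161) and the chemokine Ccl5 by -0.74 ± 0.10 (SE, adjusted p = 0.000346). Of 19 cholesterol synthesis genes, 4 fell and none rose (12 adjusted over the list alone, median -0.37, adjusted p = 1.75e-24). Of the NF-kB-driven genes 4 fell (11 adjusted over the list alone, median -0.21, adjusted p = 3.47e-16). Of the interferon-stimulated genes 1 fell (6 adjusted over the list alone, median -0.27, adjusted p = 8.70e-15) and of the NRF2 targets none passed over all genes (3 fell adjusted over the list alone, median -0.09, adjusted p = 7.09e-06). The lipid droplet list had 1 member risen (3 adjusted over the list alone, median 0.07, adjusted p = 0.00229). With the correlation estimated, these 5 lists had adjusted p values of 0.00245, 0.000358, 0.0140, 0.0172 and 0.0138. For Ddit3 the log2 difference of OA from vehicle was -0.11 (95% interval -0.33 to 0.11) and for Hspa5 0.05 (95% interval -0.11 to 0.22). The total was 7 genes without replicate 3 of vehicle, 9 without replicate 2 of vehicle 7 in a fit of the compared arrays alone and 29 with trend and robust moderation. Without replicate 2 of vehicle, list medians were -0.18 for interferon-stimulated genes, -0.16 for NRF2 targets and 0.03 for lipid droplet genes. Of the genes that passed, 28.6% rose, against 38.9% after quantile normalisation.

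LPS against vehicle gave the response to a TLR4 ligand in the same cells. Il6 stood at 9.79 ± 0.19 (SD, n = 4) with LPS and 1.72 ± 0.04 (SD, n = 3) with vehicle (adjusted p = 2.44e-20), where the vehicle level lies below the array medians and was not shown to be above background. Cxcl3 rose by 5.90 ± 0.11 (SE), Il1b by 4.56 ± 0.16 (SE) and Tnf by 1.90 ± 0.09 (SE). All 40 NF-kB-driven genes rose (40 adjusted over the list alone, median 1.93, adjusted p = 2.79e-68). All 28 interferon-stimulated genes rose (28 adjusted over the list alone, median 3.67, adjusted p = 6.45e-66), with the antiviral gene Mx1 at 5.61 ± 0.12 (SE). Of the inflammasome genes 11 of 19 rose and 4 fell (11 and 5 adjusted over the list alone, median 0.61, adjusted p = 1.91e-06), with Nlrp3 at 2.66 ± 0.09 (SE). Cell cycle genes fell in 26 of 29 cases (26 fallen and 1 risen adjusted over the list alone, median -0.72, adjusted p = 1.86e-13). Lysosomal genes fell in 18 of 28 cases (21 adjusted over the list alone, median -0.33, adjusted p = 1.12e-08), with the cholesterol transporter Npc1 at -0.79. Of the alternative activation genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0218), the risen ones including the chemokine Ccl17 at 2.51 and the cytokine signalling inhibitor Socs1 at 0.99. The median of this list was -0.01 without replicate 2 of LPS, where its test still pointed upwards (adjusted p = 0.0470), and 0.17 to 0.19 without replicate 1 or 4 of LPS or replicate 3 of vehicle. With an estimated correlation these 6 lists had adjusted p values of 1.22e-08, 6.14e-06, 0.0427, 0.00655, 0.0243 and 0.0429. Scd2 changed by -2.81 ± 0.11 (SE), and 13 of 19 cholesterol synthesis genes fell (16 adjusted over the list alone, median -0.44, adjusted p = 9.32e-07, adjusted p = 0.122 with an estimated correlation). Plin2 changed by -0.70 ± 0.08 (SE), and for Xbp1 the log2 difference was 0.09 (adjusted p = 0.535). In total 1839 genes rose and 2625 fell with a median SE of 0.13, so that 41.2% of the genes that passed had risen, against 52.0% when every array was centred on its own median.

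The 100 genes that rose most with LPS, chosen on the LPS and vehicle arrays, were followed in the fatty acid arrays, which share no array with that choice. At 5 h, 44 of them rose and 2 fell with SA against OA (54 and 3 adjusted over the list alone, median 0.38, adjusted p = 1.19e-34, adjusted p = 1.87e-05 with an estimated correlation), among them Cxcl3 and Ptgs2. At 20 h, 29 rose and 8 fell (33 and 9 adjusted over the list alone, median 0.10, adjusted p = 0.000174, adjusted p = 0.0760 with an estimated correlation). The change between the times had a median of -0.28 (adjusted p = 1.70e-08, adjusted p = 0.0113 with an estimated correlation). Of the 100 genes that fell most with LPS, 7 rose and 36 fell with SA against OA at 5 h (11 and 41 adjusted over the list alone, median -0.20, adjusted p = 3.56e-15, adjusted p = 0.00412 with an estimated correlation). At 20 h 13 of these rose and 60 fell (15 and 66 adjusted over the list alone, median -0.54, adjusted p = 2.26e-27, adjusted p = 0.000519 with an estimated correlation).

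SA and LPS, both given for 5 h by the sample labels, were also set against each other. Il6 stood at 2.02 ± 0.23 (SD, n = 4) with SA, below the array medians and so not shown to lie above background, and at 9.79 ± 0.19 (SD, n = 4) with LPS. Il1b was lower with SA by a log2 change of -5.24 and Tnf by -1.13 ± 0.08 (SE). Ddit3 was higher by 1.75 ± 0.10 (SE), Plin2 by 1.49 ± 0.08 (SE) and Scd2 by 3.30 ± 0.10 (SE). Of the NF-kB-driven genes 38 of 40 were lower with SA (38 adjusted over the list alone, median -1.63, adjusted p = 6.35e-59) and of the interferon-stimulated genes all 28 (28 adjusted over the list alone, median -3.46, adjusted p = 3.83e-65). Genes higher with SA than with LPS included 13 of 19 in cholesterol synthesis (14 adjusted over the list alone, median 0.64, adjusted p = 1.02e-09) and 17 of 28 in the lysosome (22 adjusted over the list alone, median 0.29, adjusted p = 9.02e-09). In the cell cycle list 21 of 29 were higher and 1 lower (22 and 1 adjusted over the list alone, median 0.48, adjusted p = 3.45e-08). In the test with an estimated correlation these 5 lists had adjusted p values of 3.98e-08, 6.46e-06, 0.0300, 0.0187 and 0.0270. For Hspa5 the log2 difference of SA from LPS was 0.01 (95% interval -0.15 to 0.16). In total 2584 genes were higher and 1816 lower with SA than with LPS, so that 58.7% were higher, against 47.5% when every array was centred on its own median.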

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

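The test of leaving out each vehicle array and the splits of the arrays were planned before the results were seen, and the tests of harvest time, of splits with the main effects removed, of the array that stands apart and of other cell types were chosen after the result was seen.

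The difference between SA and OA changed between 5 h and 20 h for 992 genes, as tested by the interaction. Among the lists, the median change of the difference was 0.70 for ER chaperones, 0.52 for XBP1 and degradation targets, 0.28 for NRF2 targets, -0.0685 for alternative activation (-0.14 to -0.01 with an array left out), -0.195 for LXR targets, -0.31 for macrophage identity, -0.43 for NF-kB-driven genes and -1.22 for the cell cycle. Among single genes it was 2.26 for Bex1, 2.07 for Clec4e, 1.96 for Cox6a2, 1.94 for Slc7a11, 1.90 for Chchd10 and 1.82 for the cell cycle inhibitor Cdkn1c. It was -3.34 for Ccl2, -3.07 for Ccl7, -2.92 for Bub1, -2.56 for Dab2, -2.40 for the histone gene H2ac4, whose level with SA at 20 h was 3.94, below the array medians, and -2.39 for the complement gene C1qa. A positive value can come from a rise with SA or a fall with OA. From 5 h to 20 h of OA, Clec4e changed by -2.71 and Slc7a11 by -1.49, and these falls enter their values.

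Cell cycle genes were lower with SA than with OA at 20 h, by a median of -1.37. Replicate 2 of 20 h SA stands apart from its group, and the median without it was -1.40, which argues against that array as the source. No biological explanation was tested, and a lower share of dividing cells and a lower level per cell stay open, since the arrays measure pooled RNA.

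Macrophage identity genes were also lower with SA than with OA at 20 h, by a median of -0.44. Without replicate 2 of 20 h SA the median was -0.46, so that array is unlikely to set the shift. A smaller share of macrophages beside other cell types would raise the markers of those types, and of 72 such markers 1.39% rose (1 risen, 4 fallen), with no list past the camera test upwards. Since 5 of the 6 lists lay below the median of the tested genes with OA (2.98 to 4.09 against 4.27), where a modest rise could not show, a smaller share and a change in the state of the macrophages cannot be told apart by this test. Both stay open as hypotheses.

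NF-kB-driven genes were lower with OA than with vehicle at 5 h, by a median of -0.21. Leaving out each vehicle array in turn gave -0.22, -0.20 and -0.18 as the list median, which argues against a dependence on any vehicle array alone. The series text gives 4 h for vehicle, and the list declined by a median of -0.51 from 5 h to 20 h of OA, so an earlier harvest of the vehicle could contribute. OA and harvest time cannot be told apart, since no vehicle array of another time is among the groups.

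Single arrays lay far from the rest of their group in 14 of 313 tests, where chance gives about 1 in 20, or 15.7. In 20 h SA, replicate 2 had the highest spread of gene deviations (0.215, others 0.153 to 0.161) and the highest median of tested genes (4.33, others 4.23 to 4.25). The same array had the lowest mean of the lysosome list (9.17, others 9.27 to 9.29) and the lowest Bub1 (2.29, others 3.07 to 3.22). In 5 h SA, replicate 4 had the highest cell cycle mean (6.13, others 5.99 to 6.01), replicate 1 the lowest Plin2 (10.16, others 10.25 to 10.26) and replicate 2 the lowest Cxcl3 (6.08, others 6.29 to 6.32). In 5 h OA, replicate 1 had the highest inflammasome mean (6.90, others 6.76 to 6.78) and the highest hypoxia mean (7.20, others 7.10 to 7.11), and replicate 3 had the lowest Trib3 (4.19, others 4.47 to 4.51) and the lowest Ppp1r15a (4.92, others 5.44 to 5.51). In 20 h OA, replicate 2 had the highest housekeeping mean (9.91, others 9.84 to 9.85). In LPS, replicate 3 had the lowest mean of IRE1-dependent decay substrates (6.37, others 6.45 to 6.46) and the highest mean of immediate early genes (6.79, others 6.69 to 6.71).

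Among the 12146 probe sets that are not in the probe table, and so in no comparison of genes, 1186 changed with LPS against vehicle and 504 with SA against OA at 20 h.

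For each of the 10 comparisons of a pair of groups, no other split of the arrays gave as many genes as the real one. This argues against chance in the grouping of these arrays, but 1 of 35 is the lowest value such splits can give. The other splits also mix the real groups. Fitted alone, the real split gave 2993 genes for SA against OA at 20 h and 660 at 5 h, with at most 0 and 1 in the other splits, and the value was 1 of 35 splits as large for each of the 10 comparisons of a pair of groups. Against vehicle, SA at 5 h gave 373, OA at 5 h 7, LPS 4113, SA at 20 h 2569 and OA at 20 h 1008, with at most 0, 0, 0, 0 and 1. SA at 20 h against 5 h gave 1808, OA at 20 h against 5 h 673 and SA against LPS 3664, each with at most 0 in the other splits. For the interaction, 4 of 100 drawn splits were as large, with 880 genes in the real one and 2208 in the highest other. The 3 other splits, with 1351, 2208 and 2045 genes, exchanged all 4 SA and OA labels at 20 h and 2, 1 and 1 of the 4 at 5 h. They keep the whole difference at 20 h with its sign turned, and the difference at 5 h cancels where 2 labels were exchanged and in part adds to that of 20 h where 1 was, which is a structure of the samples. Such splits test for no SA effect at either time and not for an unchanged effect, so they do not decide on chance for this count. After the main effects of acid and time were taken out of each gene, 1 of the 100 splits was as large, the real one with 880 genes. The highest other gave 104, which argues against chance for this count. However, 1 of 100 is the lowest value these splits can give, and this test was chosen after the result was seen.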

How the results depend on the processing

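Member counts without replicate 2 of 20 h SA were the alternative chosen after the result was seen; all others were planned. Counts of changed genes moved by over 1.5 times in these cases. OA against vehicle at 5 h (14 genes) gave 29 with trend and robust moderation, 7 in a fit of the compared groups alone, and 7 to 16 with an array left out. In the fit of the compared groups alone, SA against OA at 5 h gave 660 (1131) and SA against vehicle at 5 h 373 (664), and the latter gave 389 to 580 with an array left out. OA at 20 h against vehicle gave 1537 with array weights (937). The cause was not tested, except that these smaller fits have fewer arrays.

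With an array left out, the other counts were 3615 to 4336 (LPS against vehicle), 647 to 825 (OA at 20 h against vehicle), 652 to 1056 (OA, 20 h against 5 h), 874 to 1026 (interaction), 2508 to 3012 (SA at 20 h against vehicle), 2881 to 3174 (SA against OA at 20 h), 2165 to 2460 (SA, 20 h against 5 h), 3902 to 4192 (SA against LPS) and 866 to 1033 (SA against OA at 5 h).

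Neither the labels nor the values gave a pairing by replicate number for all arrays. Deviations of arrays with the same number had r above 0.1 in 10 of 55 pairs (0.139, 0.224, 0.0344 and 0.132 for SA with OA at 20 h). The median r across genes of these 55 pairs was 0.0176, against -0.00472 over 165 pairs of different number. For 10 of 23 arrays, the mean r with arrays of other groups was highest for their own number. Replicate 2 of 20 h SA, which stands apart from its group, had r of 0.224 with replicate 2 of 20 h OA and 0.232 with that of 5 h OA. Its r was 0.165 with that of LPS, 0.114 with that of 5 h SA and -0.143 with that of vehicle. A batch shared by some arrays of the same number is not excluded by these values. With the replicate block, the counts were 3313 and 1095 for SA against OA at 20 h and 5 h, 639, 16 and 4507 for SA, OA and LPS against vehicle at 5 h, 997 for the interaction, 2536 and 882 for 20 h against 5 h of SA and OA, 3205 and 907 for SA and OA at 20 h against vehicle, and 4425 for SA against LPS.

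Dnaja1 reversed for SA against vehicle at 5 h, at 0.02 (adjusted p = 0.979) with the probe set of largest variance; the cause was not tested. No list test turned its direction. List medians changed sign without a turn of the test for LXR targets, SA at 20 h against vehicle (-0.03, and 0.01 without replicate 1 of 20 h SA), and for alternative activation, LPS against vehicle (0.10, and -0.01 without replicate 2 of LPS). The call was lost in 4 with array weights, 7 with centring, 2 with the mean of probe sets, 8 in the smaller fit, 5 with the probe set of largest variance, 6 with quantile normalisation and 15 without dim genes, and in 67 with an array left out, where 1238 kept it. Lists past the test for OA at 20 h against vehicle fell from 14 to 9 without replicate 2 of vehicle. Without replicate 2 of 20 h SA, changed mitochondrial genes for SA at 20 h against 5 h went from 6 to 3, and lymphocyte genes in the interaction from 1 to 0 by limma. Among named genes, 82 calls were lost in the smaller fit (868 unchanged), 27 with centring (923 unchanged) and 418 with an array left out (7458 unchanged). Signal over background was not assessed here beyond leaving out dim genes. At the preset correlation, no alternative setting or left-out array changed a call for the LPS-responsive genes.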

Other observations

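No test below was chosen after the result was seen. From 5 h to 20 h of SA, ER chaperones rose in 14 of 20 cases (16 adjusted over the list alone, median 0.55, adjusted p = 1.61e-18). NF-kB-driven genes fell in 31 of 40 with 1 risen (31 and 1 adjusted over the list alone, median -0.96, adjusted p = 2.08e-44), with Tnf at -1.76 ± 0.08 (SE). Cell cycle genes fell in 27 of 29 cases (28 adjusted over the list alone, median -1.15, adjusted p = 1.28e-44). Hypoxia and glycolysis genes fell in 13 of 23 cases with 1 risen (15 and 1 adjusted over the list alone, median -0.43, adjusted p = 1.96e-07). With an estimated correlation these 4 lists had adjusted p values of 0.000396, 3.45e-07, 8.33e-06 and 0.00722. From 5 h to 20 h of OA, NF-kB-driven genes fell in 22 of 40 cases with 2 risen (28 and 2 adjusted over the list alone, median -0.51, adjusted p = 1.66e-34, adjusted p = 2.08e-06 with an estimated correlation), with Tnf at -1.44 ± 0.08 (SE). The cell cycle list had 1 of 29 members fallen with OA (median 0.05, adjusted p = 0.833). The lipid-scavenging receptor Olr1 and the fatty acid receptor Gpr84 fell from 5 h to 20 h of both acids, Olr1 by a log2 change of -3.55 ± 0.22 (SE) with SA and -3.85 ± 0.22 (SE) with OA, and Gpr84 by -3.95 ± 0.09 (SE) and -3.52 ± 0.09 (SE). No vehicle of 20 h is among the groups, so changes between the times within an acid combine longer treatment and time in culture. Between the times, 2552 genes changed with SA and 874 with OA.

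Against the 5 h vehicle, 3168 genes changed with SA and 937 with OA at 20 h (1537 with array weights), and treatment and time are combined in both counts. Plin2 rose by 1.06 ± 0.08 (SE) with SA and by 1.03 ± 0.08 (SE) with OA. With OA, 12 of 19 cholesterol synthesis genes fell (13 adjusted over the list alone, median -0.60, adjusted p = 1.57e-16, adjusted p = 0.00845 with an estimated correlation), and 29 of 40 NF-kB-driven genes fell (31 fell and 1 rose adjusted over the list alone, median -0.70, adjusted p = 1.19e-51, adjusted p = 1.05e-07 with an estimated correlation). With SA, 24 of 36 targets of PERK, ATF4 and CHOP rose and 1 fell (25 and 1 adjusted over the list alone, median 0.77, adjusted p = 3.31e-18, adjusted p = 0.000833 with an estimated correlation). NF-kB-driven genes fell with SA in 20 of 40 cases and rose in 5 (22 and 8 adjusted over the list alone, median -0.29, adjusted p = 8.18e-10, adjusted p = 0.00155 with an estimated correlation). Cholesterol synthesis genes fell with SA in 7 of 19 cases and none rose (9 adjusted over the list alone, median -0.25, adjusted p = 0.000397, adjusted p = 0.190 with an estimated correlation). The median of the cholesterol list was -0.15 without replicate 2 of 20 h SA. Of 16 neutrophil markers, 7 rose and 1 fell from 5 h to 20 h of SA (8 and 1 adjusted over the list alone), and 3 rose with OA (6 rose and 1 fell adjusted over the list alone). Mmp8, a neutrophil collagenase, rose by 1.18 ± 0.15 (SE) with SA and 0.93 ± 0.15 (SE) with OA. The list had adjusted p values of 0.000897 and 0.000302 (adjusted p = 0.0573 and 0.105 with an estimated correlation).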
